A study of Homo sapiens with 12 samples.

How the data were processed

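RNA from HCT116, an established human colorectal carcinoma cell line, was measured on 6 Agilent 2-colour arrays that carried 12 samples. Per the labels, the cells grew in McCoy's 5A medium with 10% fetal bovine serum and were transfected by Lipofectamine with a control or with an siRNA against SNHG1, a long noncoding RNA. Per the labels, 500 ng of RNA was labelled for each sample. There were 4 groups of 3 samples: control a, siSNHG1-a, control b and siSNHG1-b. The labels call the replicates biological and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The control was labelled with Cy3 and the knockdown with Cy5 on all 6 arrays, with no dye swap. A dye effect that belongs to a probe therefore adds to the change in each siRNA comparison, and cancels only in the difference between the siRNAs.

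The deposited scanner files hold spot intensity values on a linear scale, extracted with Feature Extraction 10.7.1.1 per the file headers. The authors' deposited value table holds log2 values with a median of 6.45 in each of its 12 columns. Each of the 12 columns correlated best, across probes, with its own channel of its own array (Spearman's rho 0.997 to 0.999), with slopes of 0.964 to 0.988 against log2 processed signal among bright probes. Their sorted values differed between columns by at most 0.0025. The scale is therefore log2 signal with nearly equal distributions; how the authors made the distributions equal is not given in the sources used here. The submitters' processing notes name limma, with no version given in the sources used here.

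Of the 180,880 spots, 4974 were control spots. The other 175,906 spots belonged to 71,816 probes with 2 to 5 spots each. The median spot signal was used where the design had named the mean signal, because the files carry the median. Background was corrected with normexp at an offset of 50, log2(Cy5/Cy3) was normalized by loess within each array with control spots at weight 0, outlier spots were left out (1.87% to 2.02% per array) and spots of a probe were averaged. No probe's spot was saturated. A probe was tested if over 0.5 of its spots were well above background in all 3 replicates of at least 1 of the 4 groups, which left 49,565 probes. Levels per channel were taken after loess and Aquantile scaling.

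The main test was limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with files read by the data.table package (1.17.8): all 6 arrays in 1 fit, a coefficient per siRNA, the array as the pairing of a knockdown with its control, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The contrasts were each siRNA, their mean and siSNHG1-a minus siSNHG1-b. These designs, the alternatives and the rule for named genes were fixed before the data were examined. Single control genes were compared with exact two-sided tests. Sign flips of the 3 replicate numbers allow no p below 0.25, and 3 arrays against 3 allow none below 0.1.

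The files name probes and do not pair them with genes. None of the probe IDs matched a symbol or accession of the RefSeq list of genes used here (assembly GRCh38.p14). By spelling alone, 110 short IDs made of letters and a number equal a synonym in it, and were not used. The unit of each test was therefore the probe. No probe was paired with SNHG1 in the sources used here, so the targeted RNA, the 23 gene lists, the choice of 1 probe per gene and the genes named in advance were not analysed here, and the knockdown itself was not checked. The array design is annotated on hg19 per the file headers, so no coordinates are given. In place of gene lists, probes were grouped by the text of their IDs (tRNA, rRNA, snRNA, snoRNA_scaRNA and others), after the files had been seen, and tested with limma's camera at a preset correlation of 0.01, adjusted over 10 classes, and again with an estimated correlation. 4 single probes are named by the ranking fixed for genes changed by both siRNAs (the smaller of the 2 absolute changes, called with both, 1 sign on all arrays, well above background in all 12 channels). Taking 2 that rose and 2 that fell, without symbols, was decided after values had been seen.

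Same-numbered arrays of the a and b pairs deviated together: the correlations of their deviations from the group means, across probes, ran from 0.21 to 0.24. The replicate number from the labels was therefore taken to pair arrays across siRNAs, though the main fit had no term for it. Replicates 1 and 2 of both pairs lay on slide 1 and replicate 3 of both on slide 2, so part of this pairing is the slide. The alternatives covered background correction, normalization, the dim-probe filter, the authors' values, blocks for replicate and slide, 1 slide alone, each array left out, the variance model and the threshold. The blocks and the variance model did not enter the camera test of classes, so its result could not differ under them.

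The fit was tested on simulated log ratios with the measured spread of the 49,565 probes, 200 of them changed. In the comparison of siSNHG1-a with its control, 25.4% of probes changed by 0.2 on the log2 scale were recovered, 100% of those changed by 0.5 and 100% of those changed by 1, and 8.54% of 164 calls were false. In the difference between the siRNAs the shares were 5.88%, 93.9% and 100%, with 5.71% of 70 calls false. The simulated noise was independent between arrays, while same-numbered real arrays deviated together. Far more than 200 probes were called in the real comparisons of each siRNA. These shares therefore need not hold for the real arrays.

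The number of arrays limits the precision. Median signals were 84 to 99 in green and 130 to 158 in red, over median backgrounds of 17 to 25 and 27 to 30. The slope of observed on expected log ratios of the spike-in RNAs, per the file headers, was 0.752 to 0.777, so these ratios as Feature Extraction gave them were compressed. The slope was not computed for the loess ratios tested here.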

Results

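The 6 arrays set SNHG1 knockdown with either of 2 siRNAs against its own control in HCT116 cells, with 3 arrays per siRNA. Of the 71,816 probes, 56.1% to 66.3% were well above background in the Cy3 channel of an array, which held the control, and 68.7% to 73.9% in the Cy5 channel, which held the knockdown. Probes carry IDs and no gene names. Most belonged to the A_ numbered (26,602 tested) and p numbered (20,819 tested) series. Smaller classes were labelled RNS (960), imsncRNA (736), snoRNA_scaRNA (255), tRNA (84), snRNA (77) and rRNA (12), and 16 probes were named by an RNA number alone.

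The first question was what changed when SNHG1 was targeted with siRNA a. tRNA probes, which read the RNAs that carry amino acids to the ribosome, were higher as a class with siSNHG1-a. Their median log2 change was 0.21 ± 0.04 (SD over arrays, n = 3), and 50 of 84 tRNA probes rose, 0 fell and 34 did not pass the test. Adjusted over the class alone, 52 rose and 0 fell. The class passed limma's camera at the preset correlation (adjusted p = 1.055e-11) and not with an estimated one (adjusted p = 0.618 with an estimated correlation). The 16 probes named by an RNA number alone had a median log2 change of 0.66 ± 0.15 (SD, n = 3), and 12 of them rose and 0 fell (adjusted p = 1.055e-11 in camera, adjusted p = 0.224 with an estimated correlation). The size depends on the scaling: as the median of the fitted changes of its probes, this class stood at 0.70, and at 0.27 with the authors' values and 1.29 with median centring, and the tRNA class at 0.23, 0.24 and 0.55. Among rRNA probes 4 of 12 rose and 1 fell (adjusted p = 0.0391 in camera, adjusted p = 0.622 with an estimated correlation), and this call was lost in 10 of 18 alternatives (adjusted p from 0.0535 to 0.630), among them median centring, Agilent's signals, the authors' values, no background correction, no filter on dim probes, and leaving out siSNHG1-a replicate 2 (adjusted p = 0.103) or siSNHG1-b replicate 3 (adjusted p = 0.0841). Probes for small nucleolar and Cajal body RNAs went both ways, with 50 of 255 higher and 34 lower. Of snRNA probes, which read RNAs of the spliceosome among others, 15 of 77 were higher and 11 lower, and neither of these classes passed camera (adjusted p = 0.752 for both). With median centring the small nucleolar and Cajal body class passed camera (adjusted p = 0.0122). Its median of fitted changes was then 0.275, against 0.023 in the main fit.

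In this comparison 16,443 of 49,565 probes passed limma at the adjusted threshold, 8779 higher and 7664 lower with siSNHG1-a. The changes were small: the median absolute log2 change over all tested probes was 0.10 with a median SE of 0.06, and 494 of the called probes changed at least 1.5-fold, 169 of them higher and 325 lower. At least a 2-fold change was seen for 77, of which 13 were higher and 64 lower. Because the dyes were not swapped, these counts include any dye effect of single probes. When the channels were treated as unpaired samples, with no block for the array, 4912 probes passed, and with median centring in place of loess 34,738 passed, of which 29,067 were higher. The 1.5-fold changes were then mostly rises, 3670 against 97 falls, and 1270 against 587 with Agilent's processed signals. These rises include a general shift, since both were centred on all spots that are not controls, dim ones included. In the mean of both siRNAs the tested probes then had a median change of 0.21 and 0.08, against 0.01 after loess. Falls at 1.5-fold were also more with Agilent's signals, 587 against 325 after loess, which an upward shift does not give. Without the replicate 2 array of this pair 10,524 passed, and without replicate 3, 9916.

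With siSNHG1-b the tRNA probes had a median log2 change of 0.07 ± 0.04 (SD, n = 3), with 33 of 84 higher, 10 lower and 41 not past the test. The class passed camera at the preset correlation (adjusted p = 0.0254) and not with an estimated one (adjusted p = 0.602 with an estimated correlation). The call was also lost without the replicate 1 array of this pair (adjusted p = 0.0800), without replicate 2 (adjusted p = 0.184) and with no filter on dim probes (adjusted p = 0.0623). The probes named by an RNA number alone had a median log2 change of 0.58 ± 0.05 (SD, n = 3), with 13 of 16 higher and 0 lower (adjusted p = 4.727e-11 in camera, adjusted p = 0.236 with an estimated correlation). The median of fitted changes was 0.61 for this class, 0.23 with the authors' values and 1.16 with median centring, and for tRNA 0.08, 0.05 and 0.35. The rRNA class did not pass with siSNHG1-b (4 of 12 higher, 2 lower, adjusted p = 0.156 in camera). It passed in 1 of 18 alternatives, the stricter filter on dim probes (adjusted p = 0.0427). Of the small nucleolar and Cajal body probes 28 of 255 were higher and 53 lower, and of the snRNA probes 24 of 77 were higher and 11 lower (adjusted p = 0.300 and 0.585 in camera). The lean of the small nucleolar and Cajal body probes depends on the scaling. Their median of fitted changes was -0.016, but 0.234 with median centring and 0.044 with Agilent's signals. In all, 17,789 probes passed limma's test, 9465 higher and 8324 lower, of which 513 changed at least 1.5-fold (171 higher, 342 lower) and 54 at least 2-fold (8 higher, 46 lower). Unpaired channels, with no block, gave 5795 calls, and median centring gave 35,042, of which 29,349 were higher. At 1.5-fold median centring gave 3981 rises and 84 falls, and Agilent's signals 1429 and 627. Here too the rises include the general shift of the tested probes. Falls with Agilent's signals were again more than after loess, 627 against 342.

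**Figure D1:**
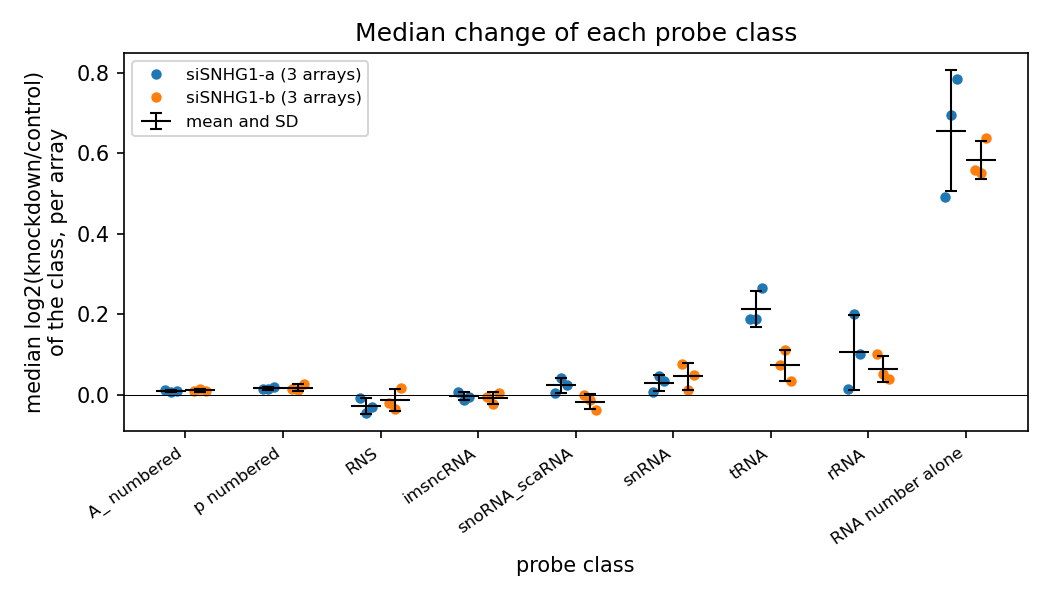
Median log2(knockdown/control) of each probe class on each array (points, 3 arrays per siRNA), with the mean and SD (black), by class on the horizontal axis. The tRNA class lies at 0.21 with siSNHG1-a and 0.07 with siSNHG1-b, and the probes named by an RNA number alone lie at 0.66 and 0.58.

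Using 2 siRNAs against 1 target asks which changes they share. By the ranking used here, the 2 strongest shared rises were those of a probe labelled rRNA and a probe named by an RNA number alone. Their IDs carry consecutive numbers, and whether they read 1 RNA was not analysed here. The rRNA class as a whole had medians of fitted changes of only 0.05 and 0.09. The probe RNA143568|rRNA_7_1559 was 4.19-fold higher with siSNHG1-a (log2 change 2.07 ± 0.12, SD, n = 3) and 3.63-fold higher with siSNHG1-b (1.86 ± 0.13), at limma adjusted p values of 1.4e-11 and 7.06e-11. RNA143567 was 4.10-fold and 3.47-fold higher (log2 2.03 ± 0.12 and 1.80 ± 0.09). With median centring the log2 changes were 2.71 and 2.49 for the first of these and 2.67 and 2.42 for the second, and with the authors' values 1.61 and 1.41, and 1.62 and 1.40. The strongest shared falls were those of A_33_P3376965, which fell by 3.84 ± 0.75 on the log2 scale with siSNHG1-a and by 2.67 ± 0.50 with siSNHG1-b, and of A_23_P21134, which fell by 2.81 ± 0.32 with siSNHG1-a and fell by 2.12 ± 0.34 with siSNHG1-b. All 4 probes had 1 sign on all 6 arrays, as the ranking required. The gene of none of them is named here.

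A run of 13 consecutively numbered p probes fell together with both siRNAs. Its median log2 change was -1.21 ± 0.09 with siSNHG1-a and -1.37 ± 0.21 with siSNHG1-b (SD over arrays, n = 3), and 9 of its 13 probes fell at least 2-fold with both. With median centring the medians were -0.77 and -0.94. The next longest run of probes called in 1 direction with both siRNAs held 6 probes.

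**Figure D2:**
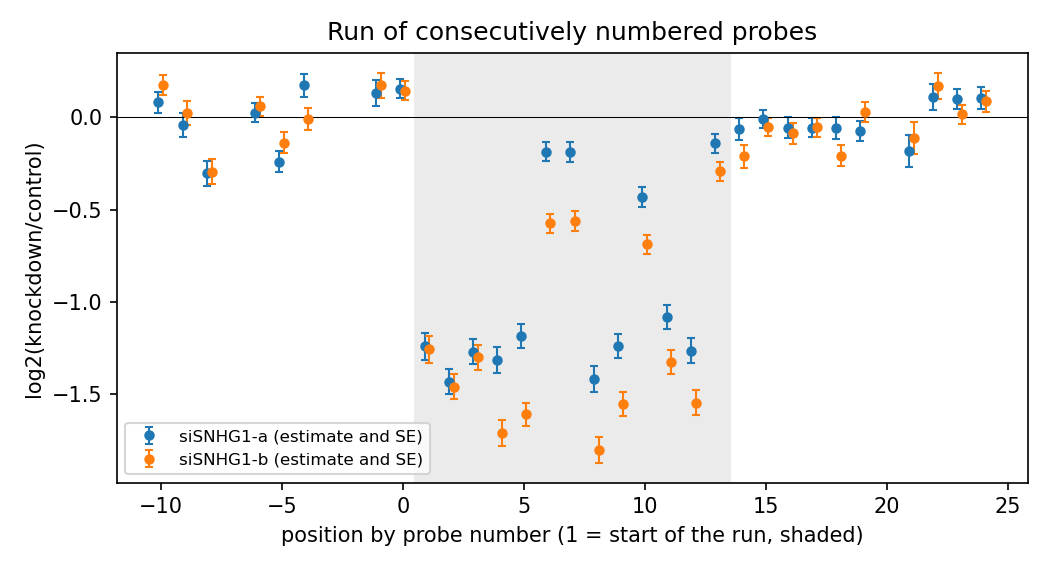
Log2(knockdown/control) with its SE for p probes in order of their number, with the run of 13 shaded, for siSNHG1-a (blue) and siSNHG1-b (orange). The probes of the run lie between -1.43 and -0.14 with siSNHG1-a and between -1.81 and -0.29 with siSNHG1-b.

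In the mean of both siRNAs 24,665 probes passed, 13,354 higher and 11,311 lower, 388 of them by at least 1.5-fold (119 higher, 269 lower). The fit took all arrays as independent, while same-numbered arrays of the 2 siRNAs deviated together (correlations from 0.21 to 0.24). Its error for the mean is therefore likely too small, and the counts of calls in the mean too high. By how much was not tested. The balance of rises and falls depends on the scaling: median centring gave 31,910 higher and 7337 lower, at 1.5-fold 3469 and 77, and Agilent's signals 16,940 and 7132, at 1.5-fold 1239 and 457. Under these scalings the median change of all tested probes was 0.21 and 0.08, against 0.01 after loess. Bright probes rose more under median centring: lists at a median log2 brightness of 16.5 had a median change of 0.82. The rises under median centring therefore go in part with brightness. The same direction was called with both siRNAs for 10,616 probes, 5621 higher and 4995 lower, and opposite directions for 230. With median centring the shared calls were 26,260 higher and 3791 lower, and with Agilent's signals 6443 and 2498. Independent lists would share 1676 higher and 1287 lower calls. Of the shared calls, 276 were at least 1.5-fold with both siRNAs (90 higher, 186 lower; 2446 and 60 with median centring, 526 and 295 with Agilent's signals) and 43 at least 2-fold (7 higher, 36 lower). Across probes, which are not independent replicates, the changes with the 2 siRNAs correlated at r = 0.773. Pairs of 1 array of each siRNA correlated at a mean r of 0.680 when they had the same replicate number and 0.618 when they had different numbers, with mean covariances of 0.0293 and 0.0267. A control RNA shared within a replicate number would add to the first of these. One shared across numbers, or a dye effect of single probes, would add to both, and the labels state no sharing. With no block for the array the mean gave 12,157 calls and the shared count was 2875.

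**Figure D3:**
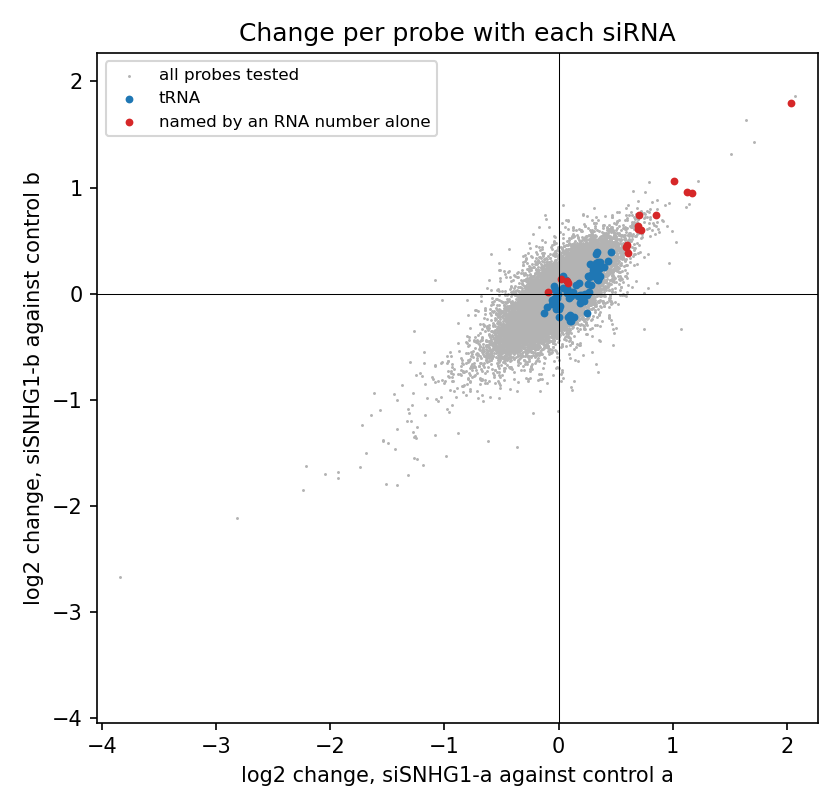
Log2 change of each of the 49,565 probes with siSNHG1-a (horizontal) and siSNHG1-b (vertical), with tRNA probes in blue and probes named by an RNA number alone in red. The changes correlate at r = 0.773 across probes, and both coloured classes lie mostly above 0 on both axes.

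The difference between the siRNAs is the comparison in which a dye effect common to all arrays cancels. The tRNA class was higher with siSNHG1-a than with siSNHG1-b by a median of 0.10 on the log2 scale (camera adjusted p = 1.619e-09, adjusted p = 0.506 with an estimated correlation), with 0 of 84 probes passing singly and 8 passing when adjusted over the class alone. Small nucleolar and Cajal body probes differed by a median of 0.04 in the same direction (camera adjusted p = 0.00373, adjusted p = 0.498 with an estimated correlation), a call also lost without siSNHG1-a replicate 2 (adjusted p = 0.0721). The probes named by an RNA number alone differed by a median of 0.10 and did not pass (camera adjusted p = 0.129, adjusted p = 0.790 with an estimated correlation), with 0 of 16 called singly; it passed in 2 of 18 alternatives, scale normalization and without siSNHG1-a replicate 1 (adjusted p from 0.0019 to 0.925 over the 18). In all, 1185 probes differed, 629 of them with a higher log ratio with siSNHG1-a and 556 with a lower one, and 8 differed at least 2-fold. A_23_P21134 fell by 0.70 more with siSNHG1-a (limma adjusted p = 0.0235) and A_33_P3376965 by 1.17 more (adjusted p = 0.0325). Both rest on replicates 2 and 3: in replicate 1 the differences were 0.06 and 0.26 the other way. Leaving out any of the 4 arrays of replicates 2 and 3 ended both calls (adjusted p from 0.0925 to 0.118 and from 0.118 to 0.153). With the replicate number as a block, 2587 probes differed, and with any 1 array left out 547 to 842. The count was 45 with Agilent's processed signals and 69 with the authors' deposited values. With no block for the array, 53 probes were higher with siSNHG1-a and 54 lower.

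Set channel against channel, control b and control a differed at 0 of 49,565 probes by limma, with 335 (0.68%) at an unadjusted p under 0.05. With the replicate number as a block they differed at 0, with 2487 (5.02%) unadjusted, about the share that no difference would give. The knockdown channels, siSNHG1-b against siSNHG1-a, differed at 446 probes (196 higher with b, 250 lower) and at 2059 with the block, with 10.3% and 17.2% unadjusted. Deviations of same-numbered samples from their group means correlated at 0.467 to 0.664 for the controls (mean 0.543). For the knockdowns they correlated at 0.288 to 0.591 (mean 0.404). Whether same-numbered controls are 1 RNA is not settled by these overlapping ranges.

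Control spots on the array read 2 genes by name. The probe Human-GAPDH_3 for GAPDH, a glycolytic enzyme often used as a reference, had a log2 change of 0.01 ± 0.02 with siSNHG1-a and 0.03 ± 0.06 with siSNHG1-b (SD, n = 3). Human-GAPDH_5 gave -0.08 ± 0.04 and -0.21 ± 0.12 and was lower on all 6 arrays (exact two-sided sign-flip p = 0.25 with same-numbered arrays turned together, the smallest 3 numbers allow). Human-PGK1_3, for the glycolytic enzyme phosphoglycerate kinase, gave -0.38 ± 0.08 and -0.11 ± 0.13, and Human-PGK1_5 gave -0.34 ± 0.12 and -0.03 ± 0.13. With median centring, which raised the median change of all tested probes from 0.01 to 0.21, Human-PGK1_3 turned to 0.14 and 0.40, Human-PGK1_5 to 0.10 and 0.41, Human-GAPDH_5 to 0.51 and 0.37, and Human-GAPDH_3 stood at 0.59 and 0.61. The exact two-sided permutation p for siSNHG1-a against siSNHG1-b was 0.1 for both PGK1 probes, the smallest 3 arrays against 3 allow (0.2 when adjusted over the 4 human control probes), and 0.25 when paired by number.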

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

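The tests of shared control RNA, of a dye effect, of turned replicate numbers for the mean and the shared calls, of brightness and loess for probes named by an RNA number alone and of the probe run were chosen after the result was seen, as were the probe classes.

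The siRNAs differed at 1185 probes by the test of their difference. The tRNA class differed by a median of 0.103 on the log2 scale, the snoRNA_scaRNA class by 0.042 and the 3 vault_RNA probes by -0.190 (siSNHG1-a minus siSNHG1-b). With an estimated correlation none of these 3 classes passed (adjusted p = 0.506, 0.498 and 0.498). Outside the measurement of the cells' RNA, 2 of the 12 ERCC control probes lay at least 1 log2 unit above the highest negative control in all 12 channels. Their mean log2 levels were 8.66 and 8.59, against 5.89 for the negative controls.

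Many small changes were shared by both siRNAs. The numbers pair the arrays, so same-numbered arrays were turned together for the mean and the shared calls. The 4 orientations or splits of each comparison are too few for a share under 0.05. In each, 1 of 4, the real one, was as large: 24,665 calls in the mean, 10,616 shared, 16,443 with siSNHG1-a, 17,789 with siSNHG1-b and 1185 in the difference, and the highest other gave 0. Except in the difference, a dye effect common to all arrays would also give more calls in the real orientation. The turned arrays therefore do not speak to it.

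A control RNA shared only within a replicate number is argued against as the whole cause by arrays of different number, which still correlated at a mean r of 0.618. One control RNA used across numbers stays open, since the labels do not exclude it. For a dye effect of single probes, neighbouring p numbered probes were compared. Uncorrected, they were about as alike in the mean change (r = 0.212) as in the difference (r = 0.209), where such an effect cancels. Corrected for noise, that shared by neighbours included, the values were 0.223 and 0.292, a ratio of 0.764 (95% bootstrap interval 0.586 to 0.989). The ratio was 0.624 with the shared noise left in, and 0.482 in the form run first, which also took all 6 arrays as independent. Each corrected ratio lies below 1, the side that a dye effect would give. A rule added after the values were seen asked that uncorrected and corrected values lie the same way. They do not, so by that rule this comparison does not decide. How much of the shared change is a dye effect and how much is left for the knockdown stays open without a dye swap.

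For the higher tRNA and number-only classes, brightness was weighed. The tRNA median with siSNHG1-a lay at the 100th percentile of 10000 lists matched on brightness, outside their 95% range of -0.04 to 0.05. For the probes named by an RNA number alone, lists from the nearest 400 probes by brightness were dimmer than the class (median log2 15.5 against 16.6). Lists from the nearest 20, a width chosen after that was seen, had 16.5, and the class median of 0.66 lay at the 100th percentile of them. Those matched lists had a median of 0.25 themselves, so part of the rise goes with brightness. With median centring in place of loess bright probes rose in general: lists matched in the same way had a median of 0.82, and the class, at 1.22, lay at their 99.97th percentile. Without loess the class thus still stood above probes as bright. The lists were drawn probe by probe, which takes the probes of a class as independent. If they are not, the percentiles of both classes are too extreme. With an estimated correlation the number-only class did not pass camera (adjusted p = 0.272 in the mean of both siRNAs). Whether loess is the whole cause of its rise is therefore not settled by these lists. A dye effect of these probes, different RNA yield and an effect of the knockdown stay open for both classes; none of the 3 was tested for them, beyond the differences between the siRNAs, where a common dye effect cancels: a median of 0.103 for tRNA, and 0.0996 for the number-only class, which did not pass camera (adjusted p = 0.129).

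For the run of 13 falling probes, a chance order of probe numbers was tested by permutation. None of 10000 shuffled orders held a run as long, and their longest was 8 (permutation p = 0.0001, the smallest they can give). A candidate explanation is that the probes read 1 RNA lowered by both siRNAs. Whether they do, and whether it is the targeted RNA, was not analysed here, since no probe is paired with a gene. Probes that overlap in sequence could also share a dye effect, which no value here decides.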

How the results depend on the processing

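The fold threshold of 2, the 1.5-fold threshold under other scalings and the recomputed class, control and single-probe values, with their differences, were chosen after seeing the data. Median centring in place of loess raised the counts to 34,738 (siSNHG1-a), 35,042 (siSNHG1-b), 39,247 (mean) and 30,051 (same way with both), and moved the share of higher calls in the mean from 54.1% to 81.3%. Agilent's processed signals gave a share of 70.4%. Without the array as a block (no replicate block) the counts were 4912, 5795, 12,157 and 2875, and the difference had 53 higher and 54 lower with siSNHG1-a. With the replicate block across siRNAs, which follows the pairing by number, the difference rose to 2587. The other 4 counts stayed within 1.5 times (20,114, 21,180, 27,548 and 13,227). That block takes the spread between replicate numbers out of the error of these 4, so it is no check of them against the pairing. The difference was 725 without background correction, 45 with Agilent's signals, 588 with scale normalization, 69 with the authors' values and 414 on slide 1 alone. On slide 1 alone the others were 11,861, 12,566, 20,059 and 7089. With slide as a block they were 18,167, 19,420, 25,467 and 11,963, and the difference 1774. The slide block likewise takes the spread between slides out of the error of the counts other than the difference. Slide 2 has 1 array per siRNA, so it gives no test. A 1.5-fold threshold left 494, 513, 388 and 276, with median centring 3767, 4065, 3546 and 2506, and with Agilent's signals 1857, 2056, 1696 and 821; an adjusted p under 0.01 left 9634, 10,655, 17,648 and 5840; a 2-fold threshold left 43 shared. The cause of these moves was not tested, apart from stricter thresholds.

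Leaving out 1 array gave 9916 to 18,042 (siSNHG1-a), 12,043 to 17,441 (siSNHG1-b), 20,869 to 23,042 (mean), 7138 to 9084 (same way) and 547 to 842 (difference). The siSNHG1-a count fell by over 1.5 times without its replicate 2 (10,524) or 3 (9916), and the difference without any array but siSNHG1-b replicate 2; each such fit has fewer arrays.

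The tRNA median with siSNHG1-b ranged from 0.053 to 0.099 with 1 array left out and was 0.040 (adjusted p = 0.0623) with no dim-probe filter. Class medians here are medians over probes of the fitted changes, not the means of array medians given with an SD. With an estimated correlation the class calls ended at unchanged medians: tRNA 0.227 and 0.075, number-only 0.70 and 0.61. Over 18 alternatives each, both classes kept their direction with both siRNAs, but not their size: the number-only medians ranged from 0.27 (authors' values) to 1.29 (median centring) with siSNHG1-a and from 0.23 to 1.16 with siSNHG1-b, and the tRNA medians from 0.17 to 0.55 and from 0.04 to 0.35. The rRNA call with siSNHG1-a was lost in 10 of the 18. The 18 include the replicate block, the slide block and the variance model, which did not enter camera and so could not end a class call. Separately, the 4 named probes kept direction and call in the settings that gave them. Red signal over background was higher than green, and dim control channels limit falls.

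The checks of SNHG1, the gene lists, named genes and 1 probe per gene were not run, since no probe is paired with a gene; testing every probe on its own is the main test here.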

Other observations

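Probes labelled RNS leaned lower after loess, the only scaling this was computed for: in the mean of both siRNAs 144 of 960 rose and 251 fell, with a median log2 change of -0.02 (camera adjusted p = 0.145). The imsncRNA probes went both ways, with 166 of 736 higher and 171 lower. The meaning of neither label is given in the sources used here.

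Within the run of 13 falling probes, the first 3 differed between the siRNAs by 0.02 to 0.03 on the log2 scale. The 10 later probes were all lower with siSNHG1-b, by 0.15 to 0.43, and 4 of them passed limma's test of the difference (adjusted p 0.0108 to 0.0497; the next had 0.0534). The lean was noticed in the values and no explanation was tested.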
